A study of Sus scrofa with 12 samples.

How the data were processed

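RNA was measured in blastocysts of the pig (Sus scrofa) obtained by parthenogenetic activation, in which an unfertilised egg is induced to develop without sperm. The labels name Smart-Seq2, a method that amplifies cDNA from very small inputs, and paired-end sequencing on an Illumina NovaSeq. The series holds 12 samples in 4 groups of 3. These are a fresh control and 3 vitrified groups, called here vitrification, vitrification I and vitrification II after the sample titles. Vitrification is rapid cooling to a glass-like state for storage. The series title names liquid helium, but the labels do not say which group it was used for. The labels name blastocyst as the source of every library, while the protocol speaks of single cells sorted into lysis buffer. If each library is 1 cell, the p-values below measure spread between cells, not between separate embryos.

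The deposited values are FPKM, that is fragments scaled to gene length and to the mapped fragments of the library, as made by the authors, with 1 value for each of 31781 Ensembl pig gene identifiers in each library. The submitters' processing notes name FastQC, TopHat2 2.0.13, Cufflinks 2.2.1 and DESeq2 without giving their roles, and no genome build is stated. The table held 11 libraries. The 3rd library of the vitrification group had no column and was not analysed here, so that group has 2 libraries where the design set out in advance had 3. No other column of per-sample values was left out, and 0 pairs of libraries were identical. Sequencing depth is unknown, because the table holds no counts. No interval or detection limit that needs a count is given.

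Values were analysed as log2(FPKM + 1) without further scaling. Genes were kept with an FPKM of at least 1 in at least 3 libraries, which left 9411 genes, of which 8158 (86.7%) carried a symbol. A linear model with 1 mean per group was fitted to all 11 libraries with limma 3.58.1 in R 4.3.3, with a mean-dependent prior for the spread (trend). Each pair of groups was tested with the moderated test of limma, two-sided, with Benjamini-Hochberg adjustment over the genes kept. A gene was called at an adjusted p under 0.05. The 3 vitrified groups together were compared with fresh control in a separate fit, and the moderated F test asked whether any of the 4 groups differed. Log2 changes are given ± SE and FPKM levels as mean ± SD. The p-values measure only the spread between these libraries, which may be technical, and the labels give no batch or date.

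Gene lists for 32 lineages and functions were fixed, and the 30 with at least 5 genes kept were tested with camera, a competitive set test in limma, at the preset correlation of 0.01 with Benjamini-Hochberg adjustment over lists. They cover trophectoderm, epiblast and hypoblast markers and markers of leukocytes and erythroid cells. They also cover pro-apoptotic and anti-apoptotic genes, heat shock chaperones, endoplasmic reticulum (ER) stress, antioxidants, nuclear oxidative phosphorylation, mitochondrially encoded genes, glycolysis, lipid storage and oxidation, cholesterol synthesis, the actin and tubulin cytoskeleton, cell junctions, and water and ion transport. Others are the DNA methylation machinery, histone modifiers, imprinted genes, DNA repair, cell cycle, autophagy and lysosome, ribosomal proteins, immediate early genes, interferon response, proteasome, splicing, and implantation signalling. A further tested list of function, which camera called higher in vitrification II against fresh control, vitrification and vitrification I, is left out of the text. Its adjusted p = 0.710, 0.943 and 0.815 with an estimated correlation in these 3 comparisons. Against fresh control its call ended without control 2, vitrification 1 or vitrification 2 (0.0557, 0.0513 and 0.0518), and against vitrification without vitrification 2, vitrification I replicate 3 and vitrification II replicates 1 and 3 (0.139, 0.0503, 0.05004 and 0.0709). The cumulus or granulosa and maternal oocyte lists had 2 genes each above the filter and are given only as mean levels per library. Lists were also tested with an estimated correlation and with fry, a rotation test of limma that asks whether the genes of a list move on balance one way.

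Genes are named in the text by a rule. It took, per comparison, the called genes with a symbol, a mean FPKM of at least 5 in the higher group and no overlap between the 2 groups' libraries, and of these the 10 largest rises and the 10 largest falls. It added up to 4 called members of each list with the largest change, and a fixed set of lineage, apoptosis, chaperone, antioxidant, DNA methylation, cold-inducible and imprinted genes whether or not they passed. For the pooled comparison and the F test it took the 10 genes with a symbol and the smallest p. The examples printed are those whose calls moved least when libraries were left out.

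Measures per library (total FPKM, genes detected, shares of FPKM and mean levels of marker lists, 12 in all) were compared by an exact permutation test of the F statistic over 92400 assignments of the libraries, which form 15400 distinct partitions, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The smallest p this test can give is 6.49e-05. Overlaps between comparisons were set beside those from 100 simulations of unchanged vitrified groups against the real control libraries. Their noise was drawn separately for each gene and library.

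The groups, comparisons, tests, filter, lists, rule for named genes and a first set of alternatives were chosen before the data were examined. These alternatives were a pseudocount of 0.1, no filter, a filter at an FPKM of 5, quantile normalization, median-ratio scaling, array weights, the replicate number as a block, each library left out, and fits on 2 groups only. Scaling to the FPKM total outside the mitochondrial genome, vitrification I replicate 2 standing alone for its group, other detection thresholds, per-library differences without each library, and the overlaps after quantile normalization were added after the data were seen.

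The procedure was tested on simulated data with 9411 genes, of which 200 were changed. At a simulated log2 change of 2 it recovered between 60% (vitrification against fresh control) and 96% (vitrification II against fresh control) of the changed genes, and at 1 it recovered between 2% and 16%. False calls made up 3.36% to 7.69% of calls. Camera recovered 3 of 3 shifted lists and called 1 other list. The simulated genes were independent of each other, so this does not test whether the preset correlation holds for the real lists.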

Results

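Gene expression was measured in 11 libraries of pig parthenogenetic blastocysts. There were 3 libraries of fresh control embryos, 2 of the vitrification group, 3 of vitrification I and 3 of vitrification II. The labels do not state how the procedures of the vitrified groups differed. The summed FPKM of a library ran from 439650 to 591894. Sequencing depth is unknown, since the deposited values are FPKM without counts. Control 1 stands for fresh control replicate 1 below, and vitrification 1 for vitrification replicate 1. Log2 changes are differences of mean log2(FPKM + 1) ± SE from limma. Levels are mean FPKM ± SD over the libraries of a group. Across the 9411 genes tested, the mean Pearson r of a library with its own group lay between 0.911 and 0.954, and with the other groups between 0.825 and 0.897. The first principal component held 40.5% of the variance and the second 20.8%. Vitrification I lay at one end of the first, from 27.2 to 79.9, and vitrification II at the other, from -65.5 to -63.9.

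The groups differed in how much of the FPKM came from the mitochondrial genome. This share was 39.9% ± 3.44 in fresh control, 45.3% ± 9.21 in vitrification, 55.7% ± 10.6 in vitrification I and 19.6% ± 2.59 in vitrification II (SD; exact permutation p = 0.00292, adjusted p = 0.0117 over 12 measures). The 50 most abundant genes of each library held 56.0% ± 0.798, 59.2% ± 4.04, 65.1% ± 9.19 and 37.8% ± 2.50 of the FPKM in the same order (adjusted exact p = 0.0131). Ribosomal protein genes held 5.69% ± 0.966, 4.73% ± 2.103, 2.68% ± 0.886 and 6.82% ± 0.529 (adjusted exact p = 0.0266). Genes with any FPKM above 0 numbered 15605 ± 382, 18126.5 ± 566, 12643 ± 1272 and 15827 ± 396 (adjusted exact p = 0.0039). Genes at an FPKM of 1 or more numbered 7117 ± 426, 8732 ± 1001, 7278 ± 499 and 8865 ± 260 (adjusted exact p = 0.0266). The summed FPKM also differed (adjusted exact p = 0.0266). No pair of groups can give an exact p under 0.1 with these numbers of libraries.

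Trophectoderm markers, which mark the outer epithelium of the blastocyst, had a mean log2 level of 5.41 ± 0.22 in fresh control, 5.45 ± 0.03 in vitrification, 4.75 ± 0.32 in vitrification I and 6.18 ± 0.23 in vitrification II (adjusted exact p = 0.00935). Markers of the epiblast and inner cell mass, from which the fetus forms, stood at 1.85 ± 0.05, 2.197 ± 0.41, 1.88 ± 0.32 and 2.68 ± 0.11 (adjusted exact p = 0.0266). Markers of the hypoblast, which lines the yolk sac, stood at 0.78 ± 0.10, 1.33 ± 0.57, 0.94 ± 0.27 and 1.68 ± 0.26 (adjusted exact p = 0.0526). In vitrification II these lists lay 0.76, 0.83 and 0.90 above fresh control, where the median of all genes tested lay 0.62 higher. In vitrification I they lay at -0.66, 0.03 and 0.16 against fresh control, and that median at -0.06. The levels are not corrected for this shift, so they do not show by themselves a change of lineage. They are means over the 18, 14 and 17 listed genes with a symbol, of which 17, 10 and 9 passed the filter. The median of all genes is taken over filtered genes only, so the list values and that median are unlike measures. Cumulus and granulosa cell markers lay between 0.51 and 0.70 in the 4 groups (adjusted exact p = 0.258), and leukocyte and erythroid markers between 1.29 and 1.40 (adjusted exact p = 0.985). Maternal oocyte transcripts lay between 0.18 and 0.46 (adjusted exact p = 0.678). CDX2, a trophectoderm transcription factor, had an FPKM of 2.89 ± 1.10 in fresh control, 3.57 ± 1.52 in vitrification, 2.60 ± 1.26 in vitrification I and 3.43 ± 1.73 in vitrification II. GATA3, which acts in the same lineage, had 31.7 ± 10.7, 27.7 ± 9.34, 45.5 ± 22.5 and 38.8 ± 13.9. NANOG, a pluripotency factor, had 0.601 ± 0.382, 4.07 ± 5.52, 0.820 ± 1.09 and 2.57 ± 3.62. None of CDX2, GATA3, NANOG and GATA6 was called in any pairwise comparison. Of the 28 genes fixed by name, BCL2, DNMT3B and TET3 lay below the filter, and POU5F1, SOX2, SOX17, HSPA1A, H19 and XIST had no identifier with that symbol.

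**Figure D1:**
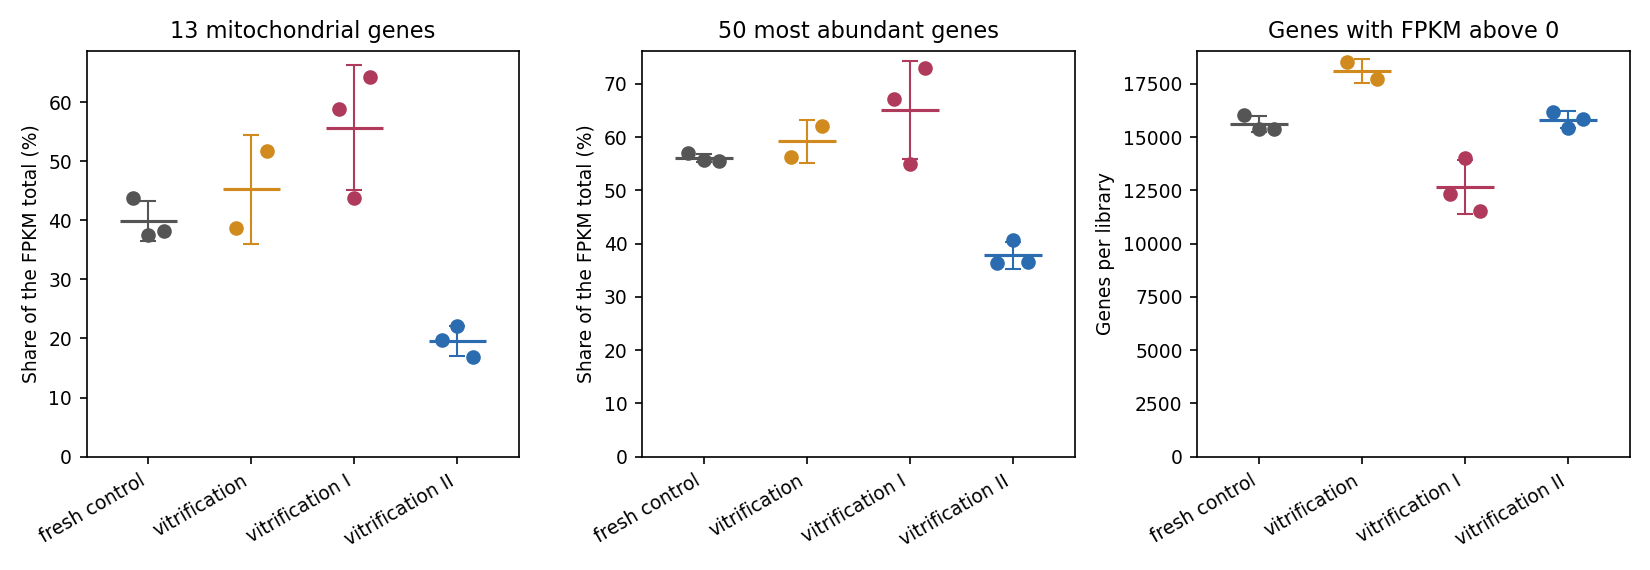
Share of FPKM from mitochondrial genes (%), share held by the 50 most abundant genes (%) and genes with an FPKM above 0, by group; points are libraries, lines means and bars SD. Vitrification II lay lowest in mitochondrial share (19.6% ± 2.59) and vitrification I lowest in genes above 0 (12643 ± 1272).

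The comparison of vitrification with fresh control asks which transcripts differed after the procedure whose title carries no further mark. Changes are relative to the median of all genes, which lay 0.19 log2 higher in vitrification. The fitted changes, on which the calls rest, are the values given plus that shift. TNFRSF21 (ENSSSCG00000001727), a death receptor, rose by 2.69 ± 0.49, from an FPKM of 7.26 ± 2.97 to 59.6 ± 25.1. B4GALT5, which makes lactosylceramide, rose by 2.66 ± 0.42, and the amino acid transporter SLC7A8 by 2.60 ± 0.47. EIF3F, a translation initiation factor, rose by 2.62 ± 0.44. EDEM1, which sends misfolded glycoproteins for degradation, rose by 2.57 ± 0.47, and SEC24D, part of the COPII coat that carries cargo out of the ER, by 2.56 ± 0.51. TXN2 (ENSSSCG00000000144), the mitochondrial thioredoxin, fell by 3.06 ± 0.41, from 76.9 ± 6.33 to 9.67 ± 1.69. CHCHD10, a protein of the mitochondrial intermembrane space, fell by 3.04 ± 0.45. The 8 calls ended without control 2 (adjusted p = 0.0762 to 0.100), without vitrification 2 (0.0994 to 0.357) and in a fit on these 2 groups only (0.0623 to 0.0865).

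Among the fixed lists, nuclear oxidative phosphorylation genes, which encode the respiratory chain, had the lowest relative median, -0.97 (camera adjusted p = 1.38e-22). With an estimated correlation the adjusted p = 0.724. Of its 55 genes 1 fell, NDUFS6, and 2 fell when adjusted over the list alone, while 23 were lower at an unadjusted p under 0.05. The NDUFS6 call (adjusted p = 0.0495) ended without control 1, control 2, vitrification 1, vitrification 2, vitrification I replicate 1 or vitrification II replicate 1, 2 or 3 (adjusted p = 0.0530 to 0.434). It also ended with the non-mitochondrial total (0.0521), a pseudocount of 0.1 (0.0682), no filter (0.0923), array weights (0.0814) and 2 groups only (0.0872). The number lower in this list was 0 without control 1 or control 2 or vitrification 2 or vitrification I replicate 1 or vitrification II replicate 2 or vitrification II replicate 3 and 2 without vitrification I replicate 2 or vitrification I replicate 3. Implantation signalling genes had a relative median of 0.78 (camera adjusted p = 0.000506, adjusted p = 0.724 with an estimated correlation, 0.121 without vitrification 2). Of its 18 genes 0 were called over all genes by limma, 5 rose when adjusted over the list alone and 9 were higher at an unadjusted p under 0.05. Camera also called the DNA methylation machinery higher (0.87; adjusted p = 0.00142, adjusted p = 0.724 with an estimated correlation). Of the 30 proteasome genes, 0 were higher and 0 lower at an unadjusted p under 0.05. Camera called this list lower (-0.66, adjusted p = 2.44e-06, adjusted p = 0.724 with an estimated correlation and 0.0806 after quantile normalization). The other lists it called were ER stress, higher (adjusted p = 0.0324, adjusted p = 0.855 with an estimated correlation, 0.532 without control 1 and 0.295 without vitrification 1), and antioxidants, cytoskeleton and ribosomal proteins, lower. These 3 had adjusted p = 0.0279, 0.00259 and 3.52e-08, adjusted p = 0.724 with an estimated correlation, 0.270, 0.664 and 0.699 after quantile normalization and 0.691, 0.853 and 0.914 without vitrification 2. Limma called 1 gene higher in the ER list, 1 lower among antioxidants and 0 in the other 2 lists. The 1 gene of the ER list and the 1 antioxidant gene were not called without control 2 or vitrification 2, nor the first without control 1.

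In all, limma called 129 genes, 118 higher and 11 lower (91.5% higher). After quantile normalization 98 were called, 69 higher and 29 lower (70.4% higher), and 73 were called both ways. The count was 0 without control 2, where 1250 genes had an unadjusted p under 0.05. It was 2 without vitrification 2, 30 without control 3, 69 without vitrification II replicate 2 and 78 without vitrification II replicate 3. It was 222 without vitrification 1 and 194 without vitrification I replicate 3.

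The comparison of vitrification I with fresh control gave large changes in both directions. MID1IP1 (ENSSSCG00000025447), a regulator of fatty acid synthesis, rose by 4.20 ± 0.49 log2, from an FPKM of 4.23 ± 2.44 to 95.3 ± 51.8 (adjusted p = 0.000160). SRPRB, a subunit of the receptor that docks ribosomes at the ER, rose by 4.14 ± 0.40, and the zinc transporter SLC30A9 by 3.99 ± 0.36. CREG1, a lysosomal glycoprotein, rose by 3.98 ± 0.46 and MGAT1, which starts complex N-glycans, by 3.89 ± 0.37. MKNK2, a kinase of the cap-binding factor eIF4E, rose by 3.87 ± 0.39, and the desmosomal cadherin DSG2 by 3.72 ± 0.40. MSX2, a homeobox factor, rose by 3.70 ± 0.37. FTL (ENSSSCG00000003153), the light chain of the iron store ferritin, fell by 4.21 ± 0.48, from 3638 ± 124 to 254 ± 227 (adjusted p = 0.000160). TXN2 fell by 3.91 ± 0.37 and the tight junction protein CLDN6 by 3.26 ± 0.47.

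Cytoplasmic ribosomal protein genes held 2.68% of the FPKM in vitrification I and 5.69% in fresh control, and mitochondrial genes 55.7% and 39.9%. Of 51 ribosomal protein genes 25 fell, 0 rose and 42 fell when adjusted over the list alone, with a relative median of -0.98 (camera adjusted p = 3.37e-13, adjusted p = 0.832 with an estimated correlation). RPLP1, of the ribosomal stalk, fell by 1.65 ± 0.35. Their number was 4 without control 2, 8 without control 3, 10 without vitrification I replicate 1 and 12 without vitrification I replicate 3. The cytoskeleton list had 12 of 29 genes lower and 1 higher (16 and 2 when adjusted over the list alone; camera adjusted p = 0.000241, adjusted p = 0.832 with an estimated correlation). Beta-actin ACTB fell by 3.16 ± 0.50, from 469.8 ± 104 to 56.0 ± 30.9, and the tubulins TUBA1B and TUBA1A by 2.71 ± 0.51 and 2.24 ± 0.44. The number lower was 6 without control 2 and 7 without vitrification I replicate 3. Nuclear oxidative phosphorylation genes had 14 of 55 lower and 0 higher (16 lower when adjusted over the list alone), among them NDUFA10 of complex I (-2.95 ± 0.38), CYC1 of complex III (-2.46 ± 0.43) and ATP5F1D of ATP synthase (-2.31 ± 0.35). Their camera adjusted p = 2.24e-05, or adjusted p = 0.947 with an estimated correlation and 0.175 after quantile normalization. The number lower was 7 without control 2, 9 without control 3 and 8 without vitrification I replicate 3.

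Glycolysis genes had 7 of 18 lower and 2 higher (the same numbers when adjusted over the list alone), with PFKL, ALDOA and ENO1 lower (-2.95 ± 0.43, -2.85 ± 0.45 and -2.72 ± 0.46). Their camera adjusted p = 0.0456, or adjusted p = 0.832 with an estimated correlation. It was 0.0869 after quantile normalization, 0.155 with vitrification I replicate 2 alone, and 0.0606, 0.0553, 0.0544 and 0.111 without control 2, vitrification 1, vitrification 2 and vitrification I replicate 1. Of the antioxidant list 8 of 26 fell and 1 rose, also when adjusted over the list alone (5 without control 3), with the glutathione peroxidase GPX1 (-2.18 ± 0.43), the glutathione synthetase GSS (-2.20 ± 0.43) and PRDX6 (-2.18 ± 0.37) lower. The camera adjusted p of the antioxidant list = 0.0101, or adjusted p = 0.832 with an estimated correlation. Trophectoderm genes had 7 of 17 lower and 1 higher (8 and 1 when adjusted over the list alone), and 4 lower without control 3. TEAD4 and ELF3 fell by 2.34 ± 0.49 and 1.95 ± 0.43, and TFAP2A rose by 3.56 ± 0.42. The camera adjusted p of this list = 0.0436, or adjusted p = 0.832 with an estimated correlation. It was 0.175 after quantile normalization, 0.0966 with vitrification I replicate 2 alone, and 0.117, 0.0597, 0.0585 and 0.0662 without control 2, control 3 and vitrification I replicates 2 and 3. The proteasome list had 3 of 30 lower and 0 higher (2 lower when adjusted over the list alone), 1 without vitrification I replicate 1 and 8 without vitrification I replicate 2. Its camera adjusted p = 0.0141, or adjusted p = 0.947 with an estimated correlation. It was 0.0975 after quantile normalization, 0.179 with the non-mitochondrial total, 0.446 with vitrification I replicate 2 alone, 0.134 without control 1 and 0.163 without vitrification I replicate 3. Junction genes went both ways, with 6 of 24 higher and 6 lower (8 and 7 when adjusted over the list alone; camera adjusted p = 0.832), and 3 higher without control 2. CLDN4 and JUP fell by 2.81 ± 0.40 and 2.57 ± 0.42. Among lipid genes the desaturase SCD rose by 2.78 ± 0.45, while the mitochondrial fatty acid oxidation enzymes ACADVL and ACADS fell by 2.61 ± 0.42 and 1.98 ± 0.40. SQLE, of cholesterol synthesis, rose by 2.195 ± 0.42.

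The ER chaperone CALR rose by 3.34 ± 0.46, from an FPKM of 224 ± 111 to 2186 ± 899. Implantation signalling genes had 5 of 18 higher and 0 lower (7 higher when adjusted over the list alone; camera adjusted p = 0.000584, adjusted p = 0.832 with an estimated correlation), with the proteoglycan SDC1 at 2.71 ± 0.36 and the integrin ITGAV at 2.39 ± 0.45. The imprinted receptor IGF2R rose by 2.28 ± 0.35 and the replication factor MCM3 by 2.54 ± 0.51. The pluripotency RNA-binding protein LIN28A fell by 2.29 ± 0.47, and the pro-apoptotic BID by 1.85 ± 0.38. Represented by vitrification I replicate 2 alone, the group no longer gave calls for RPLP1, ACTB, TUBA1B, TUBA1A, CYC1, ALDOA, ENO1, GSS, PRDX6, TEAD4, ELF3, JUP, SQLE, ITGAV, LIN28A and BID (adjusted p = 0.0683 to 0.220).

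Limma called 1752 genes, 833 higher and 919 lower, and 2099 after quantile normalization, of which 1655 were called both ways. The balance of directions rested on the scaling, since after rescaling to the total outside the mitochondrial genome 1342 of 1844 genes were higher and 502 lower, with the median of all genes at 0.26 in place of -0.06. The count was 833 without control 2, 916 without control 3 and 1026 without vitrification I replicate 1. It was 251, of which 200 were higher and 51 lower, with vitrification I replicate 2 alone, which had 14039 genes above 0 against 12340 and 11550 in the other 2 libraries of its group.

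**Figure D2:**
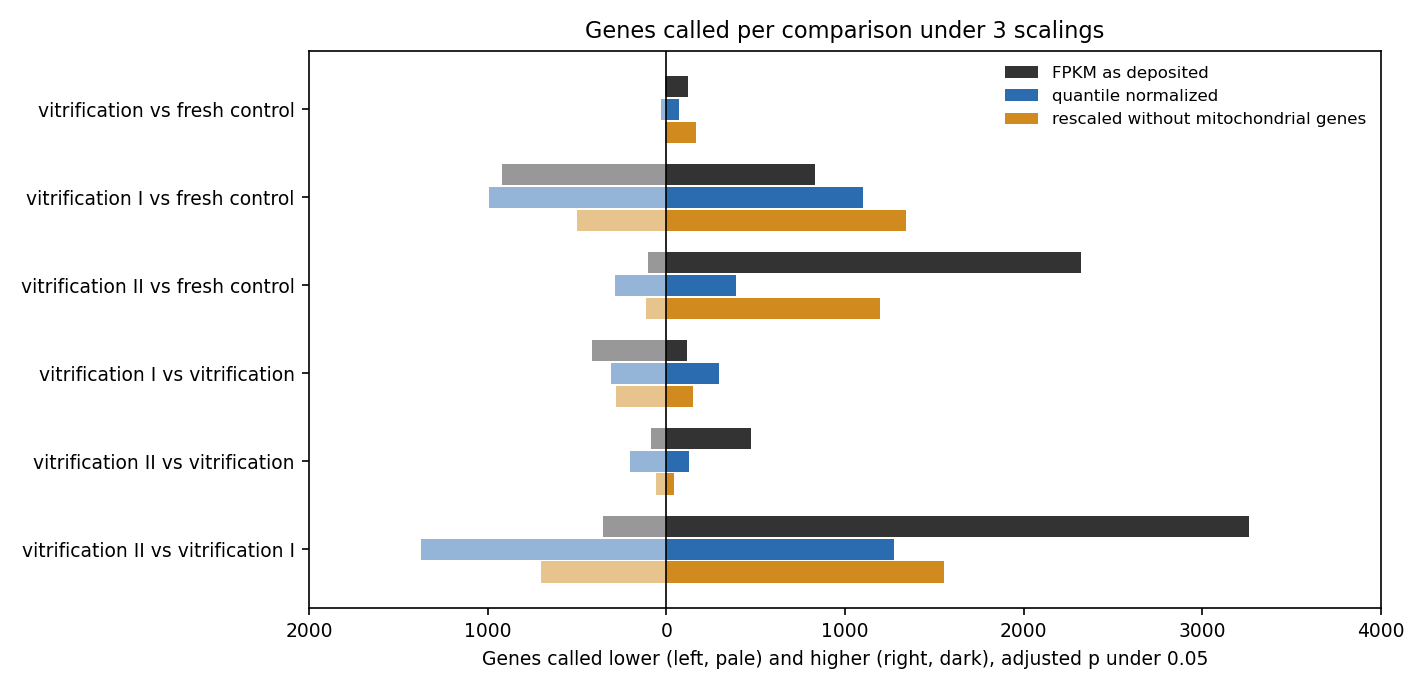
Genes called by limma in each pairwise comparison, higher to the right (dark) and lower to the left (pale), for the deposited FPKM, quantile normalization and the non-mitochondrial total. The split between higher and lower calls of vitrification II against fresh control went from 2319 and 103 to 387 and 289 after quantile normalization.

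The comparison of vitrification II with fresh control gave mostly higher calls. Changes are relative to the median of all genes, which lay 0.62 log2 higher in vitrification II. The calls rest on the fitted changes, which include that shift. The chemokine CCL1 (ENSSSCG00000017720) rose by 4.06 ± 0.52, from an FPKM of 1.00 ± 1.41 to 48.5 ± 27.0 (adjusted p = 0.000165). PGAM1, a glycolytic mutase, rose by 3.56 ± 0.38. TFRC, the transferrin receptor for iron uptake, rose by 3.29 ± 0.40, and TXNRD1, the cytosolic thioredoxin reductase, by 3.10 ± 0.47. HSD17B1, which makes estradiol, rose by 3.39 ± 0.34. MFAP5, of extracellular microfibrils, rose by 3.85 ± 0.79. CHCHD10 (ENSSSCG00000010073) fell by 2.63 ± 0.40, from 93.2 ± 17.1 to 24.1 ± 12.9 (adjusted p = 0.00334). GLRX5, needed for iron-sulfur clusters, fell by 2.54 ± 0.38.

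Of the 13 mitochondrially encoded genes 11 fell and 0 rose (12 fell when adjusted over the list alone), with a relative median of -1.86 (camera adjusted p = 1.04e-21, adjusted p = 0.101 with an estimated correlation). The share of FPKM from the mitochondrial genome was 19.6% in vitrification II and 39.9% in fresh control. ATP6 and COX2 fell by 2.28 ± 0.33 and 2.06 ± 0.31. The number lower was 6 without control 2 or control 3 and 5 without vitrification II replicate 3. After quantile normalization 0 were called, with a relative median of -0.34, and ATP6 and COX2 had adjusted p = 0.434 and 0.711. Without the filter on low values these p were 0.112 and 0.140. Quantile normalization gives each rank the same value in every library, which leaves little room for a change at the top ranks. ATP6 had an FPKM of 11743.9 or more in every library. The loss of calls after quantile normalization therefore does not test whether these genes fell. The ER list had a relative median of -1.43 (camera adjusted p = 4.06e-08, adjusted p = 0.606 with an estimated correlation). It had 4 of 26 genes lower and 3 higher, also when adjusted over the list alone, and 9 lower and 4 higher at an unadjusted p under 0.05. The number lower was 14 without control 1, 1 without control 2 or control 3 or vitrification II replicate 3 and 2 without vitrification II replicate 1 or vitrification II replicate 2, and the number higher 1 without control 2 or vitrification II replicate 2. Its SDF2L1, which works with ER chaperones, fell by 3.28 ± 0.62, and without the filter on low values the adjusted p = 0.0756. Nuclear oxidative phosphorylation had a relative median of -1.16 (camera adjusted p = 1.80e-24, adjusted p = 0.418 with an estimated correlation).

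Immediate early genes, which respond within minutes to stimuli, had 11 of 17 higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.314 with an estimated correlation). The number higher was 7 without control 2 or control 3. KLF10, IER3, DUSP1 and DUSP5 rose by 2.83 ± 0.40, 2.80 ± 0.57, 2.78 ± 0.41 and 2.75 ± 0.48. Cell cycle genes had 21 of 39 higher and 0 lower (25 higher when adjusted over the list alone; camera adjusted p = 0.00140, adjusted p = 0.710 with an estimated correlation), with MCM3, MCM4 and KIF20A at 2.05 ± 0.51, 1.81 ± 0.46 and 2.05 ± 0.45. The number higher was 7 without control 2, 8 without control 3, 12 without vitrification II replicate 2 and 13 without vitrification II replicate 3, and 5 after quantile normalization. Junction genes had 15 of 24 higher and 0 lower (17 when adjusted over the list alone; camera adjusted p = 0.00459, adjusted p = 0.410 with an estimated correlation), with the gap junction protein GJA1 at 3.04 ± 0.57 and E-cadherin CDH1 at 2.13 ± 0.40. Their number was 9 without control 2 or control 3, and 7 after quantile normalization.

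Implantation signalling genes had 11 of 18 higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.0146, adjusted p = 0.710 with an estimated correlation). Their number was 5 without control 2 or control 3 or vitrification II replicate 3 and 7 without vitrification II replicate 2, and 4 after quantile normalization. Heat shock chaperones had 11 of 25 higher and 0 lower (14 when adjusted over the list alone; camera adjusted p = 0.0405, adjusted p = 0.710 with an estimated correlation). Their number was 4 without control 2, 7 without control 3 and 6 without vitrification II replicate 3, and the camera p 0.0658, 0.0582, 0.0513, 0.0518, 0.0649, 0.105 and 0.111 without control 2, control 3, vitrification 1, vitrification 2, vitrification I replicate 1 and vitrification II replicates 2 and 3. The antioxidant list went both ways, with 4 of 26 higher and 2 lower, and tested lower (camera adjusted p = 0.0165, adjusted p = 0.710 with an estimated correlation and 0.228 after quantile normalization). Its number higher was 2 without vitrification II replicate 3, and its number lower 1 without control 2 or control 3 or vitrification II replicate 1 or vitrification II replicate 2 or vitrification II replicate 3. The prostaglandin synthase PTGS2 rose by 3.10 ± 0.55 and the urokinase PLAU by 1.61 ± 0.44. HMGCS1, of cholesterol synthesis, rose by 2.01 ± 0.53, and the lipid enzymes ACSL1 and ACLY by 2.81 ± 0.40 and 2.07 ± 0.47. Both the pro-apoptotic BID (2.11 ± 0.38) and the apoptosis inhibitor API5 (2.72 ± 0.44) rose. In the thioredoxin system TXNIP rose by 2.51 ± 0.38, while TXN2 fell by 2.33 ± 0.37. The splicing factors SF3B3 and PRPF8 rose by 2.41 ± 0.42 and 1.53 ± 0.43, and the DNA repair enzymes UNG and LIG3 by 1.93 ± 0.38 and 1.60 ± 0.41. Of the lineage genes TFAP2A, SALL4 and NID2 rose by 2.42 ± 0.42, 1.53 ± 0.35 and 1.82 ± 0.40. Of the 51 ribosomal protein genes 0 were called by limma, over all genes or over the list alone, and 1 was higher and 1 lower at an unadjusted p under 0.05. Their camera test pointed down (adjusted p = 5.41e-06, adjusted p = 0.710 with an estimated correlation), although the fitted median was 0.08 and the mean 0.03, and the relative median went from -0.54 to 0.13 after quantile normalization.

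Limma called 2422 genes, 2319 higher and 103 lower (95.7% higher). After quantile normalization 676 were called, 387 higher and 289 lower (57.2% higher), and 467 were called both ways. Median-ratio scaling gave 931, 529 higher and 402 lower, and the non-mitochondrial total 1312, 1198 higher and 114 lower. The count was 1007 without control 2, 1232 without control 3 and 1471 without vitrification II replicate 3.

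The comparison of vitrification I with vitrification rests on 2 libraries in the second group. Changes are relative to the median of all genes, which lay at -0.26 log2. MID1IP1 rose by 4.03 ± 0.55, from an FPKM of 5.42 ± 0.293 to 95.3 ± 51.8, and CREG1, MGAT1, SLC30A9 and DSG2 by 3.77 ± 0.51, 3.48 ± 0.41, 3.23 ± 0.40 and 2.66 ± 0.44. DRAM2, a lysosomal membrane protein, rose by 3.50 ± 0.42. SYNGR2 (ENSSSCG00000031600), a vesicle membrane protein, fell by 2.88 ± 0.40, from 50.8 ± 5.79 to 5.02 ± 1.57. FTL, CLDN4 and CLDN6 fell by 3.07 ± 0.54, 3.04 ± 0.44 and 2.71 ± 0.53, and BID by 2.23 ± 0.42. TNFRSF12A, a cytokine receptor, and ZYX, of focal adhesions, fell by 2.76 ± 0.38 and 2.75 ± 0.43. All but SYNGR2 of these 13 calls ended without vitrification 1 (adjusted p = 0.0521 to 0.100). All 13 ended with vitrification I replicate 2 alone (0.0602 to 0.190). Cell cycle genes had 5 of 39 lower and 0 higher (8 lower when adjusted over the list alone). Their number was 3 without control 2 or control 3 or vitrification II replicate 2 or vitrification II replicate 3, 0 without vitrification 1 or vitrification I replicate 1, 1 without vitrification 2, 11 without vitrification I replicate 2 and 2 without vitrification I replicate 3. Their camera adjusted p = 0.0249, adjusted p = 0.969 with an estimated correlation, 0.0856 without vitrification 1 and 0.244 without vitrification I replicate 3. Nuclear oxidative phosphorylation genes tested higher than other genes (relative median 0.55, camera adjusted p = 0.00789, adjusted p = 0.969 with an estimated correlation), and the p was 0.775 without vitrification 2, 0.0624 without vitrification I replicate 1 and 0.0744 without vitrification I replicate 2. Of the 55 nuclear oxidative phosphorylation genes, 4 were higher and 4 lower at an unadjusted p under 0.05. Among them NDUFA10 and ATP5F1D were called lower by limma, against the direction of the list. Both calls ended without vitrification 1, vitrification 2 or vitrification I replicate 1. Without vitrification 1 the fitted changes of NDUFA10 and ATP5F1D were -1.59 and -1.57, and without vitrification 2 -2.25 and -2.01. Without vitrification I replicate 1 the limma adjusted p = 0.0697 and 0.0567. The other lists called by camera were cholesterol synthesis, higher (adjusted p = 0.00789), and ribosomal proteins and immediate early genes, lower (0.00103 and 0.0249), with adjusted p = 0.969 for each with an estimated correlation. The p of cholesterol synthesis was 0.430 without vitrification 2 and 0.104 without vitrification I replicate 2, and that of ribosomal proteins 0.637 without vitrification 1. That of immediate early genes was 0.146 without vitrification 1 and 0.0545 and 0.0563 without vitrification I replicates 1 and 2. Limma called 1 gene of cholesterol synthesis higher, and 1 ribosomal and 4 immediate early genes lower, and these numbers were 0 without vitrification 1 or vitrification 2. In all it called 530 genes, 114 higher and 416 lower (21.5% higher). After quantile normalization it called 604, 292 higher and 312 lower (48.3% higher). The count was 353 without control 3, 7 without vitrification 1, 98 without vitrification 2, and 112, 825 and 315 without vitrification I replicates 1, 2 and 3. It was 0 with vitrification I replicate 2 alone, where 1170 genes had an unadjusted p under 0.05, and 176 in a fit on these 2 groups only.

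In vitrification II against vitrification the median of all genes lay 0.46 log2 higher, and changes are relative to it. PGAM1 rose by 3.18 ± 0.42, from an FPKM of 9.44 ± 5.06 to 125 ± 40.3 (adjusted p = 0.00153). LIN28A, TXNRD1 and the growth-arrest factor KLF10 rose by 3.62 ± 0.52, 3.004 ± 0.53 and 2.84 ± 0.45. PABPC4, which binds poly(A) tails, fell by 3.34 ± 0.40, and TXNDC5, a disulfide isomerase of the ER, by 2.97 ± 0.39. The calls of LIN28A, TXNRD1, KLF10, PABPC4 and TXNDC5 ended without vitrification 2 (adjusted p = 0.0531 to 0.0673). The ER list had 7 of 26 genes lower and 0 higher (10 lower and 1 higher when adjusted over the list alone), with a relative median of -1.89 (camera adjusted p = 4.47e-14, adjusted p = 0.547 with an estimated correlation). The number lower was 12 without control 1, 0 without vitrification 1 or vitrification 2 or vitrification II replicate 3 and 1 without vitrification II replicate 1 or vitrification II replicate 2. Mitochondrially encoded genes had 6 of 13 lower and 0 higher (12 lower when adjusted over the list alone; camera adjusted p = 4.71e-17, adjusted p = 0.182 with an estimated correlation). The number lower was 1 without vitrification 1 or vitrification II replicate 3, 0 without vitrification 2, 2 without vitrification II replicate 1 and 3 without vitrification II replicate 2, and 2 after quantile normalization. Quantile normalization leaves little room for a change at the top ranks, so its count of mitochondrial genes does not test their fall. Camera also called immediate early genes, the proteasome and splicing genes higher (adjusted p = 0.0242, 0.0116 and 0.0242), with adjusted p = 0.547, 0.943 and 0.943 with an estimated correlation. Without vitrification 2 the p was 0.166 for immediate early genes and 0.523 for the proteasome, and after quantile normalization it was 0.0596 for the proteasome and 0.170 for splicing. Limma called 4, 0 and 3 of their genes higher and 0 lower, and without vitrification 2 the numbers of immediate early and splicing genes were 0. In all it called 563 genes, 475 higher and 88 lower (84.4% higher). After quantile normalization it called 330, 125 higher and 205 lower (37.9% higher), and 204 were called both ways. Median-ratio scaling gave 119 and the non-mitochondrial total 99. The count was 306 without control 3, 56 without vitrification 1, 8 without vitrification 2, 912 without vitrification I replicate 3, and 134, 81 and 99 without vitrification II replicates 1, 2 and 3.

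Vitrification II against vitrification I had 3614 calls, more than any other pairwise comparison of the deposited values. Vitrification II against fresh control had more with array weights (4954 against 3847), with vitrification I replicate 2 alone (2837 against 789) and without vitrification I replicate 3 (2716 against 2685). The median of all genes lay 0.68 log2 higher in vitrification II. Changes are relative to that median. LIN28A (ENSSSCG00000003557) rose by 4.04 ± 0.47, from an FPKM of 0.830 ± 0.723 to 50.6 ± 28.9 (adjusted p = 2.43e-05). ZYX rose by 4.04 ± 0.39, and BID by 3.90 ± 0.38, from 0.631 ± 0.509 to 37.0 ± 2.72. PPP1R15A, a phosphatase subunit that restores translation after stress, rose by 3.92 ± 0.53, and TXNRD1 by 3.90 ± 0.47. PRSS8, an epithelial protease, rose by 3.70 ± 0.55. HSD17B1 was listed at 0 in all vitrification I libraries and at 23.3 ± 7.33 in vitrification II. ERO1B (ENSSSCG00000010148), an ER oxidase for disulfide bonds, fell by 4.25 ± 0.36, from 16.9 ± 3.79 to 0.490 ± 0.0559 (adjusted p = 2.50e-05). DERL3, of ER-associated degradation, fell by 4.15 ± 0.50, and ST6GALNAC1, a sialyltransferase, by 3.70 ± 0.45. The protein kinase C isoform PRKCB fell by 3.61 ± 0.47.

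The ER stress list had 12 of 26 genes lower and 3 higher (13 and 4 when adjusted over the list alone), with a relative median of -2.02 (camera adjusted p = 3.63e-09, adjusted p = 0.815 with an estimated correlation). The number higher was 1 without vitrification I replicate 3 or vitrification II replicate 1. The co-chaperones DNAJB9 and DNAJC3 fell by 3.67 ± 0.48 and 3.66 ± 0.51, the ER HSP90 paralog HSP90B1 by 3.61 ± 0.58 and SDF2L1 by 3.55 ± 0.62. The HSP90B1 level went from 1801 ± 339.6 to 236 ± 42.3. HSP90B1 and SDF2L1 were no longer called with vitrification I replicate 2 alone (adjusted p = 0.0872 and 0.0688). Mitochondrially encoded genes had 10 of 13 lower and 0 higher, also when adjusted over the list alone (6 without vitrification I replicate 1). Their camera adjusted p = 1.71e-13, adjusted p = 0.261 with an estimated correlation and 0.0522 after quantile normalization. That scaling leaves little room for a change at the top ranks, so its value is a weak test here. ND4 of complex I fell by 3.23 ± 0.35.

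**Figure D3:**
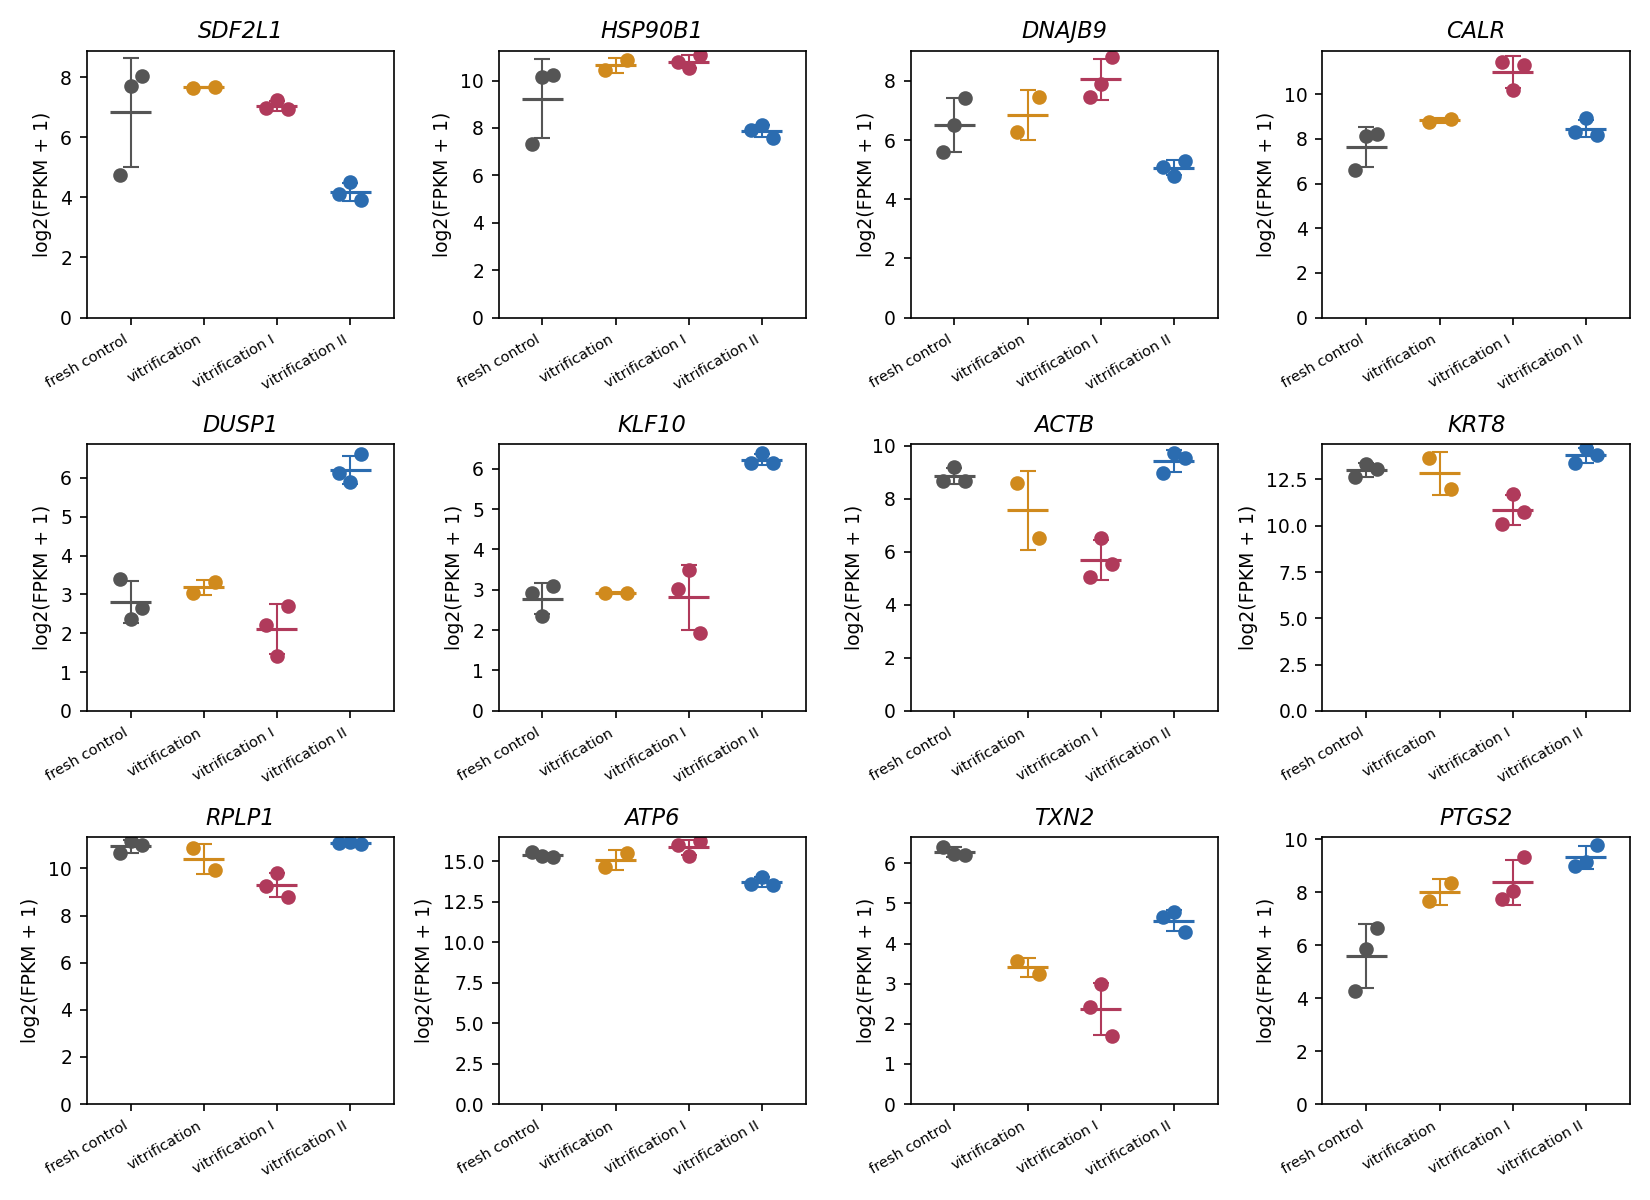
Log2(FPKM + 1) of 12 genes in each library by group; points are libraries, lines means and bars SD. HSP90B1 had an FPKM of 1801 ± 339.6 in vitrification I and 236 ± 42.3 in vitrification II, and ACTB 56.0 ± 30.9 and 702 ± 185.

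Immediate early genes had 13 of 17 higher and 0 lower (15 higher when adjusted over the list alone; camera adjusted p = 0.000691, adjusted p = 0.261 with an estimated correlation), with DUSP1, KLF10 and ZFP36 at 3.42 ± 0.41, 2.73 ± 0.40 and 2.68 ± 0.46. Cytoskeleton genes had 20 of 29 higher and 0 lower (21 when adjusted over the list alone; camera adjusted p = 0.00356, adjusted p = 0.815 with an estimated correlation), with ACTB at 3.04 ± 0.50 and TUBB2A at 1.99 ± 0.45. Cell cycle genes had 28 of 39 higher and 0 lower (29 when adjusted over the list alone; camera adjusted p = 0.00209, adjusted p = 0.815 with an estimated correlation), with MCM7, MCM4 and CDC20 at 2.99 ± 0.51, 2.88 ± 0.46 and 2.86 ± 0.48. Their number was 17 without vitrification I replicate 3 and 14 after quantile normalization. Splicing genes had 18 of 29 higher and 0 lower (19 when adjusted over the list alone), with SNRPA at 2.44 ± 0.39. Their camera adjusted p = 0.0277, adjusted p = 0.815 with an estimated correlation, 0.133 with the non-mitochondrial total, 0.0573 with vitrification I replicate 2 alone and 0.0789 without vitrification I replicate 3. Ribosomal protein genes had 33 of 51 higher and 0 lower (41 when adjusted over the list alone; camera adjusted p = 0.000691, adjusted p = 0.859 with an estimated correlation). Their number was 20 without vitrification I replicate 3, 23 after quantile normalization, 7 with the non-mitochondrial total and 0 with median-ratio scaling. Nuclear oxidative phosphorylation tested lower (camera adjusted p = 0.00809, adjusted p = 0.870 with an estimated correlation, 0.0536 and 0.072 without vitrification I replicates 1 and 2, 0.0648 without vitrification II replicate 3), with a fitted median of -0.04 and a mean of 0.24. NDUFA10 and ATP5F1D rose by 2.23 ± 0.38 and 1.36 ± 0.35.

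Camera called 9 of the 30 lists, of which 8 are described here, and did not call the other 21. Junction genes had 15 of 24 higher and 1 lower (16 when adjusted over the list alone; camera adjusted p = 0.0675), with CLDN4, JUP and CLDN6 at 3.33 ± 0.40, 3.17 ± 0.42 and 2.79 ± 0.47. Heat shock chaperones had 14 of 25 higher (17; 0.0675, in the same order), trophectoderm genes 9 of 17 (10; 0.120) with ELF3 at 2.74 ± 0.43 and TEAD4 at 2.32 ± 0.49, and glycolysis genes 9 of 18 (9; 0.120) with ALDOA at 2.94 ± 0.45 and PKM at 2.47 ± 0.52. Autophagy and lysosome genes had 15 of 29 higher (15; 0.229), with GABARAPL1 at 1.81 ± 0.53, and lipid genes 13 of 28 (15; 0.193), with ACSL1 at 2.32 ± 0.40, and 1 lower (2 without vitrification I replicate 2 and 0 without vitrification II replicate 1). The antioxidant list had 11 of 26 higher (13; 0.565), with KEAP1 at 2.48 ± 0.39, and 1 lower (2 without vitrification I replicate 3). Pro-apoptotic genes had 9 of 21 higher (9; 0.839) and 2 lower (1 without control 2 or control 3 or vitrification I replicate 1 or vitrification I replicate 3 or vitrification II replicate 1 or vitrification II replicate 2), while the anti-apoptotic list (relative median -0.16, 0.839) held BCL2L1 at 2.69 ± 0.37 and BIRC5 at 2.37 ± 0.54. The proteasome list had a relative median of 0.17 (0.120), which turned to -0.03 with median-ratio scaling.

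For the remaining lists the relative median and camera adjusted p were as follows. Leukocyte and erythroid markers had -0.39 (0.185; 0.01 with median-ratio scaling), implantation signalling -0.48 (0.229) and imprinted genes -0.79 (0.229), with NAP1L4 at 2.58 ± 0.46. Cholesterol synthesis had -0.12 (0.419), the interferon response 0.26 (0.456) with IRF7 at 1.92 ± 0.38, and water and ion transport -0.17 (0.565). Epiblast genes had 0.05 (0.695) with SALL4 at 1.63 ± 0.35, and hypoblast genes 0.06 (0.848) with NID2 at 1.86 ± 0.40. Histone modifiers had -0.19 (0.845) with PRMT1 at 2.72 ± 0.48, DNA repair -0.20 (0.848) with FEN1 at 2.39 ± 0.38, and the DNA methylation machinery 0.15 (0.848).

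**Figure D4:**
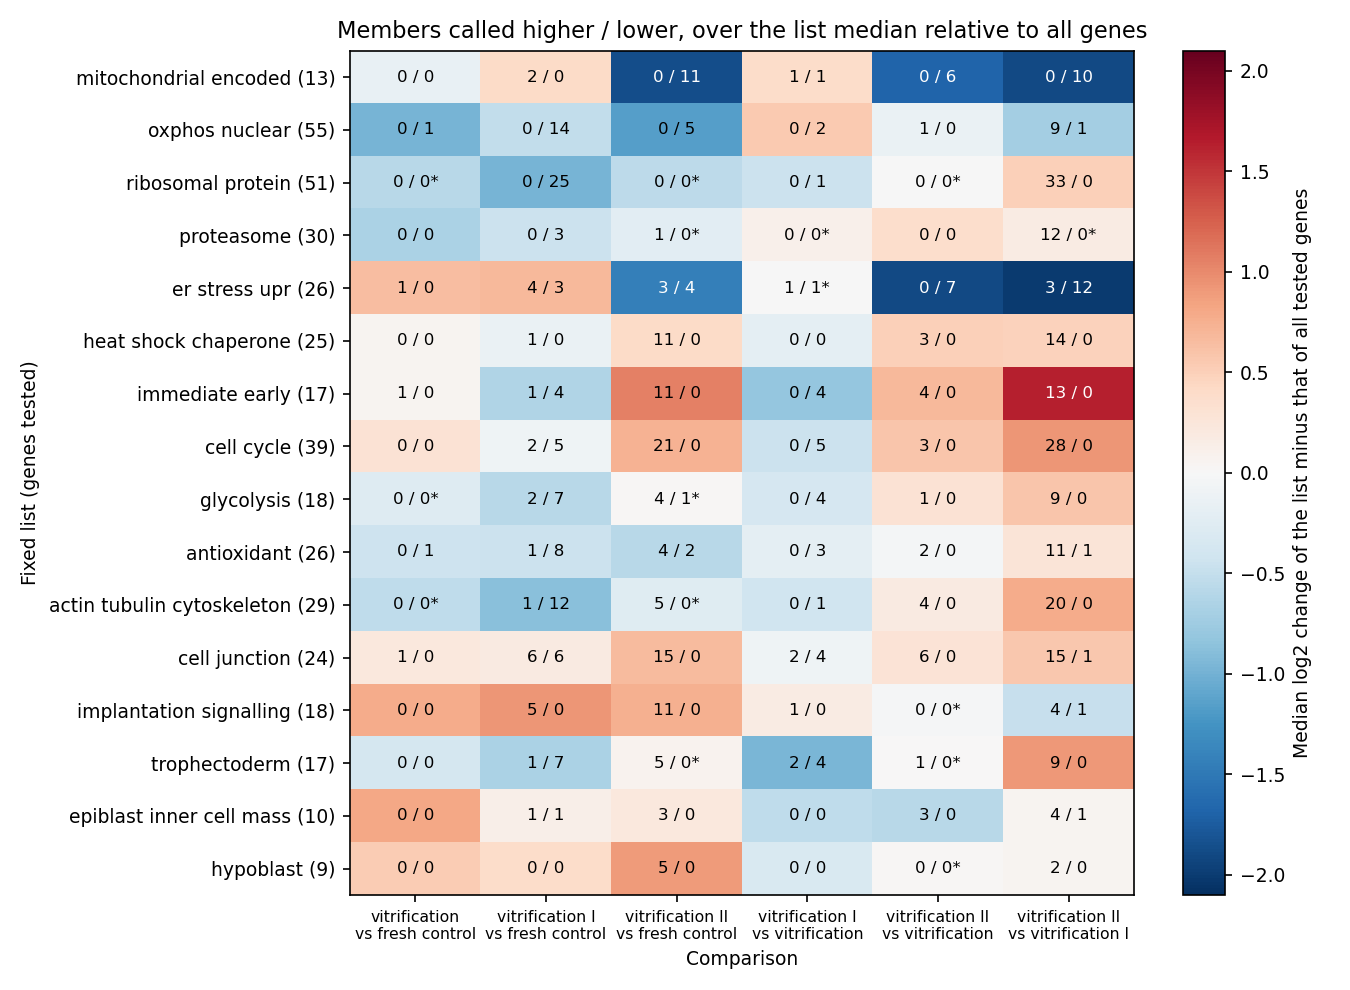
Median log2 change of 16 gene lists minus that of all genes tested (colour), with the numbers of genes higher and lower (text), in 6 pairwise comparisons. An asterisk marks the 15 of 96 cells whose sign changes under at least 1 of the other 3 scalings; the ER stress list in vitrification II against vitrification I stood at -2.02.

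Limma called 3614 genes between vitrification II and vitrification I, 3261 higher and 353 lower (90.2% higher). After quantile normalization it called 2649, 1276 higher and 1373 lower (48.2% higher), and 1623 were called both ways, 1276 higher and 347 lower. The non-mitochondrial total gave 2257, and vitrification I replicate 2 alone 789. No list of the 30 stayed called with an estimated correlation in any pairwise comparison, where 0, 0, 3, 0, 2 and 2 lists had an unadjusted p under 0.05 in the order of the comparisons above. Fry called 0, 0, 21, 1, 8 and 23 lists in that order. It tests a list against no change and not against the other genes. The median of all genes lay 0.62 and 0.68 higher in the comparisons with 21 and 23 lists. These counts therefore do not show that the lists moved apart from the other genes.

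The 3 vitrified groups together differed from fresh control in 82 genes, 72 higher and 10 lower (87.8% higher), with the median of all genes 0.28 log2 higher. After quantile normalization 64 were called, 32 higher and 32 lower (50% higher), and 34 were called both ways. Changes here are relative to that median. MKNK2 rose by 2.89 ± 0.45 (adjusted p = 0.0314), the splicing regulator ESRP1 by 1.93 ± 0.35, and the laminin chain LAMC1 by 2.04 ± 0.40. PTGS2 rose by 2.76 ± 0.54, the integrin ITGA6 by 1.88 ± 0.40, and CHCHD10 fell by 2.83 ± 0.42. The importin KPNA4, the ubiquitin ligase exchange factor CAND1, the Rap1 activator RAPGEF2 and the adaptor AFAP1L2 rose by 2.12 ± 0.43, 1.74 ± 0.35, 2.07 ± 0.42 and 2.13 ± 0.43. The number of calls was 3 without control 1, 0 without control 2 and 0 without control 3, where 824 and 979 genes had an unadjusted p under 0.05. It was 248 without vitrification 1 and 29 without vitrification 2, 35 without vitrification I replicate 1 and 0 without vitrification I replicate 2, where 1571 were under 0.05 unadjusted. It was 5 without vitrification II replicate 2 and 0 without vitrification II replicate 3, where 1550 were. All 10 calls named here therefore ended without control 2, control 3, vitrification I replicate 2 or vitrification II replicate 3. LAMC1 and AFAP1L2 were not called after quantile normalization (adjusted p = 0.0782 and 0.0621). The F test across the 4 groups called 4016 genes, with 2927 after quantile normalization and 2327 both ways. Its smallest p values belonged to HSD17B1, TNFRSF12A, ZYX, BID, SLC30A9, PGAM1, MGAT1, the phosphatase subunit PPP2R1A, SYNGR2 and the endosomal RAB5B (adjusted p from 2.66e-05 to 9.47e-05). TNFRSF12A stood at an FPKM of 49.3 ± 17.8 in fresh control, 70.5 ± 7.87 in vitrification, 7.81 ± 0.772 in vitrification I and 169 ± 34.9 in vitrification II.

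The genes called against fresh control were compared between the vitrified groups. Vitrification and vitrification I shared 56 genes higher and 11 lower, where 10.4 and 1.07 are given by chance. Vitrification and vitrification II shared 64 higher and 5 lower (chance 29.1 and 0.12), and vitrification I and vitrification II 405 higher and 36 lower (chance 205 and 10.1). In simulations with these 3 controls and no real change the shared calls numbered on average 0 and 0, 0 and 0.01, and 0.01 and 0.01. The simulated noise was separate for each gene and library. It held no shift of a whole library, so these simulations do not show how much overlap such shifts would give. After quantile normalization the shared numbers were 39 and 23, 13 and 17, and 138 and 94. Across genes the covariance of the changes was 0.386, 0.272 and 0.243 in the same order, against a mean of 0.092 over 100 simulations for each pair (0.083 to 0.103 over all). Pearson's r was 0.56, 0.48 and 0.31, against simulated means of 0.45, 0.45 and 0.50. Genes are not independent replicates, and part of the overlap may come from the shared controls, since 3 controls cannot be split between 2 comparisons. Of the 56 genes 33 were also higher in vitrification II, and 10 were lower in vitrification II than in both other vitrified groups.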

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

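The tests on other splits of the libraries for gene counts, on the mitochondrial share, on abundant genes lower in vitrification I, on trophectoderm factors and on ER genes moving with all genes were chosen after the results were seen. Values here are fitted log2 changes, without the median of all genes taken off.

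Effects of the vitrified groups against the same fresh controls differed from each other, as tested by limma between the groups directly. Between vitrification I and vitrification II, 128 genes were called in opposite directions against fresh control, 124 lower in vitrification I and higher in vitrification II and 4 the other way. The 4 were DNAJB9, ND4L, ND4 and DERL3. These opposite calls depended on the scaling, as counted after the results were seen. Of the 128, 10 stayed opposite after quantile normalization, 8 with median-ratio scaling, 41 after rescaling to the total outside the mitochondrial genome and 8 with vitrification I replicate 2 alone. The split of 124 and 4 became 14 and 10 after quantile normalization, 14 and 6 with median-ratio scaling and 37 and 8 with the non-mitochondrial total, so the direction is not a finding apart from the scaling. Between vitrification and vitrification II there was 1 such gene, ENSSSCG00000044155, which has no symbol, at -1.87 and 1.61. Among named genes lower in vitrification I and higher in vitrification II, the direct difference was 4.73 for LIN28A, 4.598 for PPP1R15A, 4.58 for BID, 4.02 for CLDN4 and 3.85 for JUP. It was 3.68 for MCM7, 3.54 for CDC20, 3.42 for ELF3, 3.37 for BCL2L1, 3.36 for ZFP36 and 3.16 for KEAP1. It was 3.12 for SNRPA, 2.60 for IRF7 and 2.55 for ATG4B. The other way it was -2.55 for ND4 and -2.00 for ND4L. After quantile normalization the calls between vitrification II and fresh control ended, among others, for BCL2L1 (adjusted p = 0.0863), PPP1R15A (0.0882) and LIN28A (0.0532). Between vitrification I and fresh control the call of BCL2L1 ended without control 2 (0.0531) or control 3 (0.0741), and that of CDC20 without vitrification I replicate 1 (0.0520) or replicate 3 (0.0538). The ER stress list was called higher by camera in vitrification against fresh control and lower in vitrification II against fresh control, and the direct comparison of vitrification II with vitrification gave an adjusted p = 4.47e-14. With an estimated correlation that adjusted p = 0.547, and it was 0.855 and 0.606 for the 2 groups against fresh control. The higher call in vitrification turned to a relative median of -0.15 without control 1 (adjusted p = 0.532) and ended without vitrification 1 (0.295), so whether the ER list moved in opposite directions stays open.

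Splits of the same libraries into other groups were counted for each model across genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split alone (1 of 10) gave 1752 genes for vitrification I against fresh control, where the highest other split gave 3. It alone (1 of 10) gave 2422 genes for vitrification II against fresh control (highest other 1) and 3614 for vitrification II against vitrification I (highest other 0). For the fixed lists, 5 of 10 splits gave as many as the 8 of vitrification I against fresh control (highest other 12). For vitrification II against fresh control 1 of 10 gave as many as 11 (highest other 10), and for vitrification II against vitrification I 2 of 10 gave as many as 9 (highest other 9). For the 4 groups 1 of 100 splits gave 4016 genes and the highest other gave 788, which argues against chance there. Only these 100 of 15400 possible splits were counted. A technical difference that coincides with the groups was not tested by it. For all vitrified libraries against fresh control 3 of 100 splits gave at least the 82 genes of the real split. The highest other split called 1936, several times the real count. Which libraries that split set apart was not examined, so the reason stays open.

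Most genes called between vitrification II and fresh control were higher in vitrification II (2319 of 2422). The smaller mitochondrial share, a few very abundant genes and a factor common to all genes were weighed as technical explanations. After rescaling to the total outside the mitochondrial genome the median change stayed at 0.50 (0.41 to 0.64 with 1 library left out), and outside the 50 most abundant genes at 0.45 (0.37 to 0.58), which argues against the first 2 as the whole of it. The median log2 ratio of group means was 0.91 in the least abundant of 3 equal bins of genes and 0.26 in the most abundant. The difference of 0.65 (0.57 to 0.83) argues against a common factor as the whole of it. Median-ratio scaling, which divides each library by its own factor, gave 529 genes higher and 402 lower, with a median change of 0.03. Quantile normalization gave 387 higher and 289 lower. The one-sided split thus depended on the scaling, and a common factor as a part of it stays open. A difference between the groups in the RNA content or the library preparation stays open, and the biological difference that the groups name was not tested apart from these.

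Of the genes called between vitrification I and fresh control, 919 were lower, among them ribosomal proteins, ACTB and glycolytic enzymes. Of the 942 genes most abundant in vitrification and vitrification II, each with a mean FPKM of at least 60.01 there, 21.2% (9.34% to 30.1% with 1 library left out) were called lower, which argues against loss of low-abundance genes as the whole of it and leaves it open for less abundant genes, while a median of -0.29 (-0.49 to -0.09) in the most abundant of 3 equal bins, where genes went both ways, decided nothing. After rescaling to the total outside the mitochondrial genome 54.5% of the 919 (44.7% to 61.4%) stayed called lower. The median change of the 919 went from -1.60 to -1.27 with a mean SE of 0.42 both times. Rescaling takes such a dilution away. The 501 genes that stayed called therefore argue against dilution by mitochondrial transcripts as the whole of it. Dilution as a part of it, and for the other genes, stays open. Whether there were fewer trophectoderm cells stays open too, because the trophectoderm transcription factors had a median of -0.0921 (-0.28 to 0.17), with TEAD4 lower and TFAP2A higher. The biological difference between the groups stays open beside these.

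ER chaperones were lower in vitrification II than in vitrification I, with a list median of -1.33 (-1.47 to -1.10 with 1 library left out). The median of all genes was 0.68 (0.56 to 0.81), on the other side of 0, which argues against a factor common to all genes. With all libraries 12 of 26 members were called lower and 3 higher, and at least 12 were lower whichever library was left out (12 to 15), which argues against 1 library deciding it. Library preparation that differed between the groups stays open, and the biological difference that the groups name was not tested apart from it.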

How the results depend on the processing

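The non-mitochondrial total, vitrification I replicate 2 alone, the other detection thresholds and the per-library differences without each library were chosen after the data were seen. Vitrification had 2 libraries, so leaving out 1 left a lone library, which is assumed to vary like the other groups, as is vitrification I replicate 2 when it stands alone. Depth is unknown, and expression near an FPKM of 1 limits the changes that can be seen. The alternatives planned for each result were run, except that only 11 of the 12 planned libraries could be left out. Counts of lists called by camera were not made with the other pseudocount, the other filters, median-ratio scaling, array weights or 2 groups only, and the vitrified groups together were not fitted as 2 groups only. Where a value below differs from the main count, the cause was not tested, except that fewer libraries give less power in the settings that leave some out.

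With each of the 11 libraries left out in turn, the count of genes lay from 0 to 222 for vitrification against fresh control, 833 to 2032 for vitrification I against fresh control and 1007 to 2716 for vitrification II against fresh control. It lay from 7 to 825 for vitrification I against vitrification, 8 to 912 for vitrification II against vitrification and 2685 to 3879 for vitrification II against vitrification I. It lay from 0 to 248 for all vitrified groups and 2966 to 4299 for the F test. Lists called lay from 4 to 10, 6 to 9, 9 to 12, 2 to 7, 5 to 14 and 8 to 10 in the order of the 6 pairwise comparisons. The list counts outside 1.5 times the main count were 4 without vitrification 2 in the first, 3 and 2 without vitrification I replicates 1 and 2 in the fourth, and 14 without vitrification 1 in the fifth.

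In this paragraph the comparisons against fresh control are named by the vitrified group alone. With a pseudocount of 0.1 the calls numbered 68 for vitrification, 48 for vitrification II against vitrification and 314 for all vitrified groups. With no filter they numbered 656 for vitrification, 906 for vitrification I, 1419 for vitrification II, 921 for vitrification I against vitrification, 944 for vitrification II against vitrification and 15 for all vitrified groups. With a filter at an FPKM of 5 and thus fewer genes tested, they numbered 81 for vitrification, 1536 for vitrification II, 127 for all vitrified groups and 2676 for the F test. Quantile normalization gave 676 for vitrification II and 330 for vitrification II against vitrification, and median-ratio scaling 931 and 119. Array weights gave 677 for vitrification, 3337 for vitrification I, 4954 for vitrification II, 2799 for all vitrified groups and 6154 for the F test. The non-mitochondrial total gave 1312 for vitrification II, 99 for vitrification II against vitrification, 2257 for vitrification II against vitrification I and 234 for all vitrified groups. Vitrification I replicate 2 alone gave 251 for vitrification I, 0 against vitrification (1170 at an unadjusted p under 0.05), 1036 for vitrification II against vitrification, 789 for vitrification II against vitrification I, 228 for all vitrified groups and 2447 for the F test. A fit by limma on 2 groups only gave 0 for vitrification (1861 at an unadjusted p under 0.05), 176 for vitrification I against vitrification and 1060 for vitrification II against vitrification. The replicate number as a block gave 55 for vitrification, 296 for vitrification I against vitrification and 2 for all vitrified groups, and 3 lists for vitrification I against vitrification. The numbers do not pair the libraries, since 2 of 15 pairs with the same number had a residual r over 0.1 (range -0.16 to 0.14) and 3 of 11 libraries correlated best with their own number.

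With an estimated correlation camera called 0 lists in each of the 6 pairwise comparisons, with 0, 0, 3, 0, 2 and 2 at an unadjusted p under 0.05. Fry called 0 for vitrification (7 unadjusted), 0 for vitrification I (9 unadjusted), 21 for vitrification II, 1 for vitrification I against vitrification and 23 for vitrification II against vitrification I. Fry does not take off the shift of all genes, so its counts are not like those of camera. Quantile normalization gave 5 lists for vitrification I and 3 for vitrification II against vitrification.

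Some results reversed, and the ranges here are over each library left out. The relative median of the ER list in vitrification against fresh control was -0.15 without control 1 (-0.15 to 1.01). That of the ribosomal list was 0.0674 in the same comparison without vitrification 2 (-1.23 to 0.0674), 0.13 in vitrification II against fresh control after quantile normalization and 0.156 in vitrification I against vitrification without vitrification 1 (-1.11 to 0.156). That of nuclear oxidative phosphorylation in vitrification I against vitrification was 0.0188 without vitrification 2, where the camera test pointed lower (0.0188 to 0.957). The mitochondrial share of vitrification minus fresh control was -1.16 points without vitrification 2. Genes detected in vitrification I minus fresh control were -16.2 without control 2, -99.7 without vitrification I replicate 2 (-99.7 to 398) and -1119 at an FPKM of 0.1. In vitrification II minus vitrification they were -575 without vitrification 1, -5.5 without vitrification II replicate 1 (-575 to 841) and -1336 at an FPKM of 0.1.

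Among genes, lists and differences taken singly, 9761 values stayed as they were, 2227 kept their direction without passing the threshold, 16 moved and 12 reversed, none of the 12 a named gene. Of the named genes called, 93 of 133 for vitrification II against vitrification I stayed called with each library left out and under all 3 scalings. The numbers were 73 of 112 for vitrification I, 55 of 121 for vitrification II, 1 of 70 for vitrification I against vitrification, 1 of 68 for vitrification II against vitrification, 0 of 21 for vitrification and 0 of 10 for all vitrified groups.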

Other observations

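The tests of the 2 hypotheses below were written before their results were seen. Genes fixed by name also covered apoptosis, cold response, oxidative defence and DNA methylation. RBM3, a cold-inducible RNA-binding protein, had an FPKM of 197 ± 42.8 in fresh control, 217 ± 3.81 in vitrification, 73.3 ± 27.8 in vitrification I and 271 ± 130.5 in vitrification II. Between the last 2 it rose by 1.85 ± 0.39 fitted log2 (n = 3 and 3, limma adjusted p = 0.00226), and the adjusted p = 0.0599 with median-ratio scaling. CIRBP, the related cold-inducible protein, stood at 5.01 ± 2.47, 6.89 ± 0.840, 2.76 ± 0.749 and 6.02 ± 3.08 in the 4 groups and was called in no comparison. The pro-apoptotic BAX stood at 4.76 ± 2.12, 3.03 ± 0.109, 3.15 ± 1.93 and 13.9 ± 5.48. It rose by 1.86 ± 0.44 between vitrification I and vitrification II, with an adjusted p = 0.0583 after quantile normalization and 0.215 with vitrification I replicate 2 alone. The chaperone HSPA8 stood at 1205 ± 289, 890.5 ± 209, 662 ± 218 and 2160.1 ± 199.8.

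The superoxide dismutase SOD1 stood at 14.9 ± 9.13, 11.6 ± 0.479, 9.56 ± 3.23 and 15.1 ± 11.5 in fresh control, vitrification, vitrification I and vitrification II, and catalase CAT at 44.6 ± 14.4, 22.3 ± 0.180, 36.6 ± 33.3 and 39.4 ± 2.31. Neither was called in any pairwise comparison. The maintenance methyltransferase DNMT1 stood at 1.00 ± 0.294, 4.43 ± 4.12, 1.37 ± 0.687 and 5.31 ± 4.01, the de novo enzyme DNMT3A at 1.69 ± 0.638, 4.76 ± 2.64, 2.11 ± 0.968 and 6.89 ± 1.99, and the demethylating TET1 at 15.8 ± 6.25, 30.5 ± 12.6, 27.4 ± 3.08 and 26.1 ± 2.39. TET1 was called in no comparison. The imprinted IGF2R stood at 1.01 ± 0.115, 6.03 ± 2.67, 8.90 ± 2.48 and 2.21 ± 0.157. Between vitrification I and vitrification II it fell by 1.60 ± 0.35 fitted log2, and with vitrification I replicate 2 alone the adjusted p = 0.0998.

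The 2 vitrification libraries differed from each other, with a mitochondrial share of 38.7% and 51.8%. A hypothesis was that vitrification 2 lies from vitrification 1 in the direction in which vitrification I lies from fresh control. Across the 9411 genes the 2 differences correlated with r = 0.33 (Spearman's rho 0.38). With the direction from vitrification I to vitrification II the first difference correlated with r = -0.24. Both directions contain the vitrification I libraries, with opposite signs. This value therefore cannot say whether the alignment was particular to the first direction. Genes are not independent replicates, and 1 pair of libraries shows no cause.

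In fresh control, SDF2L1 had an FPKM of 26.03 in control 1, 209 in control 2 and 261 in control 3, and HSP90B1 158, 1151 and 1214. A hypothesis was that control 1 lies from the other 2 in the direction in which vitrification II lies from vitrification I. Across genes the correlation was 0.0635 (rho 0.0184), which argues against it.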
